A study of Mus musculus with 6 samples.

How the data were processed

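Total RNA of bone marrow derived macrophages was extracted with TRIzol and made into libraries with the VAHTS Universal V6 kit, per the labels' protocols. The authors deposited 1 table of raw read counts per gene for 6 libraries, 3 from mice with floxed Trmt61a and LysM-Cre (KO) and 3 from mice with floxed Trmt61a alone (WT). Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with genome build mm10. Their versions, the annotation release, the strand setting and any filter on genes are not given in the sources used here. The values were whole numbers that summed to different totals between 37021855 and 41033179 per library. A strand setting that is not known leaves reads of overlapping and antisense genes unresolved, and counting by gene can split or drop reads shared by paralogs. Genotype and replicate number came from the sample titles and genotype labels.

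Of 16519 genes in the table, 16437 were matched by Entrez Gene ID to a RefSeq annotation of GRCm38.p6, the assembly of mm10, and 16305 of these were protein coding. Coordinates come from that annotation. Mitochondrially encoded genes were not analysed here. Counts of each pair of replicates were compared with a chi-square test over genes, which gave between 11.4 and 34.2 per degree of freedom, so that no pair agreed within sampling noise and each library counted once.

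The test was edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by genotype (minimum count 10), estimateDisp, robust quasi-likelihood fits in legacy mode and the quasi-likelihood F test of KO minus WT. P-values were adjusted by Benjamini-Hochberg over 12605 genes, with a threshold of 0.05. The standard error is the size of the log2 fold change divided by the square root of F, and intervals are at 95%. Counts-per-million values (CPM) use TMM-scaled library sizes. The common biological coefficient of variation was 0.122. A count of 3 corresponds to between 0.0731 and 0.0810 CPM in these libraries, and such floors cover counting error only. Single values were compared with an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

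Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. Of 42 lists fixed before the data were examined, 2 were checks (sex-linked and housekeeping genes) and 38 of the others had at least 5 tested genes; p-values were adjusted over these 38. In all 13 lists passed, 8 upward and 5 downward, and with an estimated correlation 0 passed, the smallest adjusted p being 0.733, while 1 had an unadjusted p under 0.05. The estimate was 0.35 for interferon-stimulated genes, 0.52 for cholesterol biosynthesis and 0.56 for fibroblast, stromal and endothelial markers. It was 0.12 for oxidative phosphorylation and -0.03 for the m1A enzymes. Where the estimate lay above 0.01, the preset value treated the genes of a list as more independent than estimated. Housekeeping genes had a median log2 fold change of 0.03. The 15 lists described at gene level were picked after the list results were seen. Named genes followed a rule fixed before the data were examined: Trmt61a, Trmt6 and Lyz2; because fewer than 5 genes passed, the 10 genes with the smallest p among those with a gene symbol and a mean of at least 1 CPM; up to 4 members with the smallest p of each described list; and Xist and Y-linked genes. Other genes named were chosen after their values were seen.

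On simulated counts with 200 of 12605 genes changed, the same steps recovered 70.1% of genes changed 1.5-fold, 80.6% at 2-fold and 92.4% at 4-fold, with 5 false calls among 167. These simulated libraries varied independently from gene to gene, unlike the real ones. A simulated 1.25-fold fall of the interferon-stimulated list was called, together with 1 list that was not planted (chemokines and chemokine receptors, which shares 1 lowered gene), and without a change 0 of 38 lists were called. On the real data the chemokine list did not pass (camera adjusted p = 0.492).

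The alternatives were other normalizations, count filters, tests (DESeq2 1.42.0, limma voom, and fry, which asks whether the genes of a list move one way and does not compare them with other genes), a replicate block, a minimum fold change and leaving out each library. Alternatives added after the data were seen left out KO 1 and WT 2 together, took the first component of within-genotype deviations as a covariate, left out robust estimation, left Lyz1, Lyz2 and Trmt61a out of the lists, and removed trends with transcript length and GC content (Biostrings 2.70.1, GENCODE M21 transcripts), with camera run on log2 CPM values. The covariate is centred within each genotype, so it can take up spread among libraries of a genotype but not the difference between genotypes, and it was derived from the same counts that it was then used to test. Hypotheses of the closing section were tested on lists of hepatocyte, tissue-resident macrophage and glucocorticoid-induced genes. These hypotheses came from reading the genes with the smallest p. The members' own values had not been looked up when the lists were written, and genes with at least 10 counts in total entered that fit.

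The test of liver RNA for Cd163 was changed after its result was seen. It first compared the summed excess of the hepatocyte genes in WT with the excess of Cd163, and the test given in its place leaves out WT 2; both argued in the same direction and both are reported. For the liver-expressed genes themselves, the bounds written before the result are used. They were for a time made stricter, once the result was known, by also asking for the pattern without WT 2. That stricter version was withdrawn, and the value without WT 2 is given as a description. For the resident macrophage and glucocorticoid lists, the medians met bounds written before the result to exclude each explanation; these exclusions were given up after the result was seen, because the lists hold none of the genes called lower. The pattern was also split into Cd163 and the liver-expressed genes at that point.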

Results

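Gene expression was measured by bulk RNA sequencing in mouse bone marrow derived macrophages (BMDMs), which are macrophages grown in culture from bone marrow cells. In 3 libraries the cells came from mice with floxed Trmt61a and LysM-Cre (KO), and in 3 libraries from mice with floxed Trmt61a and no Cre (WT). Trmt61a encodes the catalytic subunit of the enzyme that methylates adenosine to N1-methyladenosine (m1A) in tRNAs, and Trmt6 encodes its partner subunit. LysM-Cre is a Cre recombinase inserted into the Lyz2 gene, which deletes floxed genes in myeloid cells. The libraries held between 37021855 (WT 1) and 41033179 (WT 3) gene counts. The labels do not say whether the 3 libraries of a genotype came from separate mice or cultures, so the p-values measure only the spread between these libraries, which may be technical. Averaged over the 6 libraries, Psap, Ctsb, Lyz2, Apoe and Fth1 were the most abundant transcripts, which encode lysosomal, lipid transport and iron storage proteins; in KO, Lyz2 lay below Ctsd and Ftl1. Psap stood at 20125 ± 557 CPM (counts-per-million) in KO and 19177 ± 496 in WT (SD, n = 3).

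Trmt61a (Entrez Gene 328162, chromosome 12, 111678105 to 111683902, mm10) was lower in every library labelled KO. Its level was 0.608 ± 0.128 CPM in KO and 4.64 ± 0.648 CPM in WT (SD, n = 3), so that KO kept 13.1% of the WT level. The log2 fold change was -2.92 with a standard error of 0.28 (edgeR adjusted p = 0.00219). Between 20 and 30 Trmt61a counts stood behind each KO value and between 155 and 208 behind each WT value. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Trmt6 (chromosome 2, 132804207 to 132816054) was at 23.9 ± 0.633 CPM in KO and 24.3 ± 2.48 CPM in WT (SD, n = 3), with a log2 fold change of -0.03 and a 95% interval from -0.23 to 0.17.

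The first question was which transcripts differ between KO and WT macrophages. Only the KO mice carried Cre, so no difference given here can be assigned to the loss of Trmt61a rather than to Cre. Besides Trmt61a, 3 genes passed the threshold, and Lyz1 was the only one of the 4 that rose. Lyz1, a lysozyme gene, rose from 30.7 ± 4.24 CPM in WT to 193 ± 15.3 CPM in KO (SD, n = 3), a log2 fold change of 2.65 with a standard error of 0.10 (edgeR adjusted p = 6.34e-06). Lyz2, the lysozyme gene that carries the Cre insertion, fell from 18874 ± 2120 CPM to 9503 ± 1161 CPM (SD, n = 3), which is 50.4% of the WT level, with a log2 fold change of -0.99 and a standard error of 0.10 (edgeR adjusted p = 0.00735). Cd163, the scavenger receptor for haemoglobin bound to haptoglobin, fell from 27.4 ± 4.41 CPM to 8.70 ± 0.481 CPM (SD, n = 3), with a log2 fold change of -1.65 and a standard error of 0.13 (edgeR adjusted p = 0.000337). Each of these differences went the same way in every library, with no overlap between genotypes. Lyz2 (chromosome 10, 117277541 to 117282272) and Lyz1 (chromosome 10, 117287795 to 117292868) are neighbouring paralogs, so their counts are uncertain where reads could come from either. Cd163 (chromosome 6, 124304636 to 124330529) overlaps the predicted gene Gm52877, and the strand setting of the counting is not given in the sources used here.

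**Figure D1:**
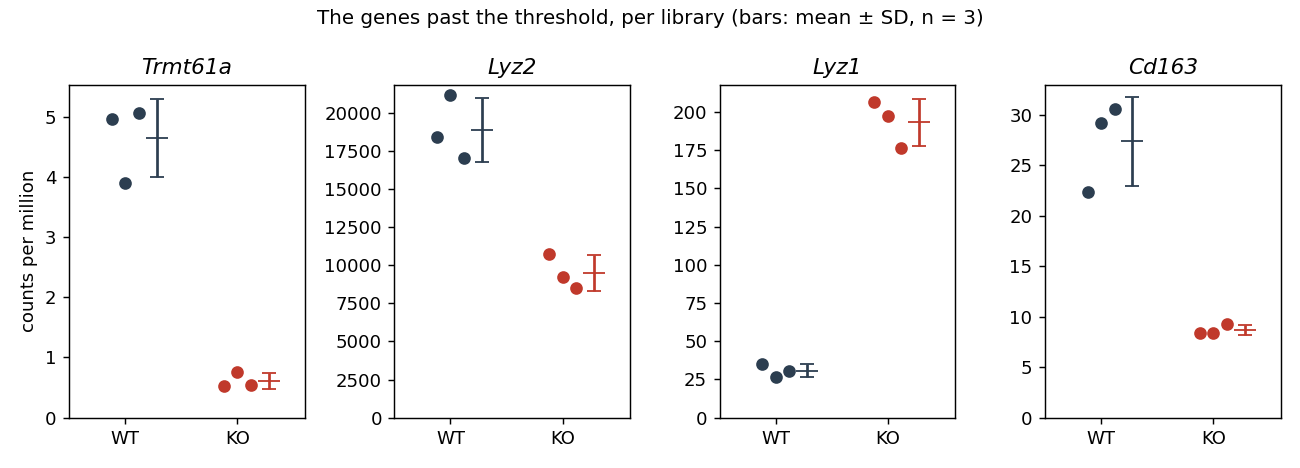
Level of Trmt61a, Lyz2, Lyz1 and Cd163 in CPM (linear axes from 0) in each WT and KO library, with points for libraries and bars for the mean ± SD of 3 libraries. For each gene the KO points lie apart from the WT points, higher for Lyz1 (193 against 30.7 CPM on average) and lower for the others.

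In total 4 of 12605 tested genes passed, 1 higher and 3 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 391 genes, 184 higher and 207 lower, where 630 are expected by chance. Dependence between genes widens the spread around that number. KO and WT values did not overlap for 8.65% of tested genes, where chance gives 10%. Of the 11345 tested genes with a mean of at least 1 CPM, 80.4% had a 95% interval within 1.5-fold in either direction and 93.5% within 2-fold. The call for Lyz2 was lost without KO 2 (edgeR adjusted p = 0.147) or without WT 1 (0.0671), although its log2 fold change stayed at -0.97 and -1.01. A minimum log2 fold change of 1 also left Lyz2 out, at -0.99. Over its 16 alternatives the adjusted p of Lyz2 ran from 1.74e-20 to 0.147, and the number of genes called ran from 3 to 31.

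**Figure D2:**
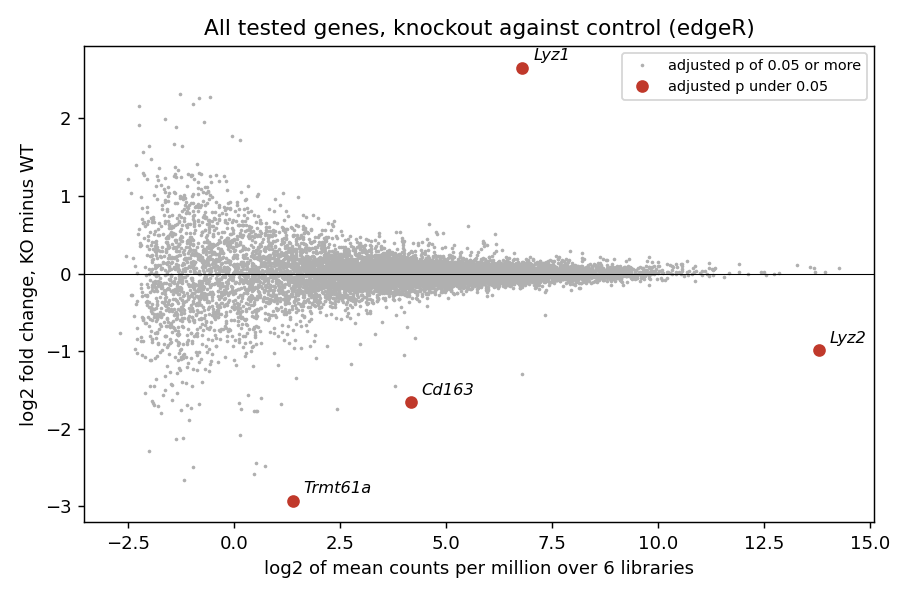
Log2 fold change (KO minus WT) of each of the 12605 tested genes against the log2 of its mean level in CPM over 6 libraries. The 4 genes with an adjusted p under 0.05 are named, and the scatter of the other genes narrows with rising abundance.

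The 6 genes with the next smallest p among those eligible to be named, all with lower values in KO, did not pass. They were Kcna2, a voltage-gated potassium channel gene (log2 fold change -1.75, edgeR adjusted p = 0.0759), Sema6d, a semaphorin gene (-0.78, 0.176), Slc1a3, a glutamate transporter gene (-2.58, 0.176), Timd4, a receptor gene for phosphatidylserine on dying cells (-2.44, 0.478), Col14a1, a collagen gene (-2.07, 0.735), and Gfra2, a receptor gene for neurturin (-1.76, 0.735). Kcna2 was at 2.47 ± 0.969 CPM in KO and 8.33 ± 0.718 CPM in WT (SD, n = 3). Timd4 was at 0.445 ± 0.114 CPM in KO and 2.43 ± 1.26 CPM in WT (SD, n = 3). DESeq2 called 17 genes, including all of these 6 and the 4 above, and all 6 also passed in edgeR with the first component of within-genotype deviations as a covariate, added after the data were seen. That covariate was derived from the same counts, so passing with it is not independent support, here or for the genes and lists below. Kcna2 further passed in edgeR with no low-count filter (adjusted p = 0.00455), with the replicate block (0.0434), without KO 1 (0.0472), without KO 2 (0.0304) and without KO 1 and WT 2 together (0.0281), within a range from 4.49e-08 to 0.861. Slc1a3 passed in edgeR with no low-count filter (adjusted p = 0.0276), within a range from 5.02e-05 to 0.99984.

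The series title asks about interferon associated genes, and 3 of the gene lists fixed before the data were examined cover them. The labels do not say whether the cells were given any stimulus. No interferon-stimulated gene passed among 64 tested members, and the list as a whole lay slightly lower in KO, with a median log2 fold change of -0.09 and lower values for 54 members (camera adjusted p = 0.00109). With an estimated correlation the call was lost (adjusted p = 0.741). Irf9, a subunit of the factor that transmits type I interferon signals, was at 51.0 ± 2.74 CPM in KO and 57.8 ± 2.70 CPM in WT (SD, n = 3), with a log2 fold change of -0.18. Ifi209 and Ifi211, members of a family of DNA-binding proteins, had log2 fold changes of -0.20 and -0.22, and Dhx58, an RNA sensor gene, had 0.16. Of the 63 members with at least 1 CPM, 47 had a 95% interval within 1.5-fold and 62 within 2-fold. The difference between genotypes in the mean of the list was -0.08 on the log2 scale, against standard deviations of 0.14 among KO and 0.10 among WT libraries. The call was lost without KO 3 (camera adjusted p = 0.779) or without WT 3 (0.583), and over 16 alternatives the adjusted p ran from 6.32e-09 to 0.839. Members of multigene families such as Ifi209 and Ifi211 may share reads with close copies.

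Components of interferon production and signalling were also slightly lower as a list, with 23 of 32 members below 0 and a median of -0.03 (camera adjusted p = 0.0126, adjusted p = 0.739 with an estimated correlation). Irf9 and Ifngr2, a chain of the interferon gamma receptor, had the smallest p of this list, and Ifngr2 was at 180 ± 4.38 CPM in KO and 195 ± 4.80 CPM in WT (SD, n = 3), with a log2 fold change of -0.12. Tlr3, a sensor of double-stranded RNA, had -0.25 and Ptpn6, a phosphatase gene, -0.12. This list lost its call without KO 3 (camera adjusted p = 0.679) or without WT 2 (0.142), within a range from 0.00101 to 0.739 over 16 alternatives. GTPases and regulators induced by interferon gamma did not pass as a list, with 14 of 25 members above 0 and a median of 0.01 (camera adjusted p = 0.780). Gbp8, Igtp, Gbp9 and Irgm2, all GTPase genes, had log2 fold changes of -0.55, -0.21, 0.13 and -0.10. In each of the 3 interferon lists 0 members passed over all genes in edgeR, DESeq2 or limma voom, and 0 passed in edgeR adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 3 interferon-stimulated genes, 2 signalling components and 0 genes of the interferon gamma list.

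Antigen presentation genes did not pass as lists. The class I list had 18 of 22 members above 0 and a median of 0.04 (camera adjusted p = 0.0680), and the class II list had 10 of 15 members above 0 and a median of 0.12 (camera adjusted p = 0.124). H2-M3, Tap1, Canx and H2-D1 of the class I list had log2 fold changes of 0.22, 0.13, 0.08 and 0.08. In the class II list, Ifi30, a lysosomal thiol reductase gene, was at 268 ± 24.0 CPM in KO and 218 ± 22.5 CPM in WT (SD, n = 3), with a log2 fold change of 0.29 that did not pass. With the added covariate Ifi30 passed (edgeR adjusted p = 0.000447), within a range from 0.000447 to 0.999965. Cd86 and Cd80, which encode co-stimulatory ligands, had 0.19 and -0.17. H2-Oa, at 0.269 CPM in KO and 0.402 CPM in WT, had -0.58 with a standard error of 0.63. The class II list passed with the stricter count filter (camera adjusted p = 0.0318), with the replicate block (0.0103), without KO 1 (0.0183), without WT 3 (2.90e-07) and with the added covariate (5.60e-05), within a range from 2.90e-07 to 0.863. The class I list passed without KO 3 (camera adjusted p = 0.0329), without WT 3 (0.00963) and with the added covariate (0.0432), within a range from 0.00963 to 0.739.

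Inflammatory cytokines and NF-kB targets lay lower as a list, with 24 of 31 members below 0 and a median of -0.09 (camera adjusted p = 0.0126, adjusted p = 0.733 with an estimated correlation). None of its members passed, and 2 had an unadjusted p under 0.05 in edgeR. Those were Bcl3, a nuclear co-regulator of NF-kB (log2 fold change -0.20), and Il18, a cytokine gene at 7.68 ± 0.803 CPM in KO and 10.1 ± 1.76 CPM in WT (SD, n = 3; -0.39). Nfkb2 and Il1b had -0.13 and -0.44. The list lost its call without KO 3 (camera adjusted p = 0.132), without WT 2 (0.240) or without WT 3 (0.106), within a range from 0.000325 to 0.733. Genes of alternative activation did not pass as a list (median 0.02, 18 of 33 members above 0, camera adjusted p = 0.144). Cd163 was the only member to pass, over all genes and adjusted over the list alone. Cd209f, a lectin gene, had -1.53 with a standard error of 0.56, Clec7a, the beta-glucan receptor gene, -0.19, and Ppargc1b 0.24.

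**Figure D3:**
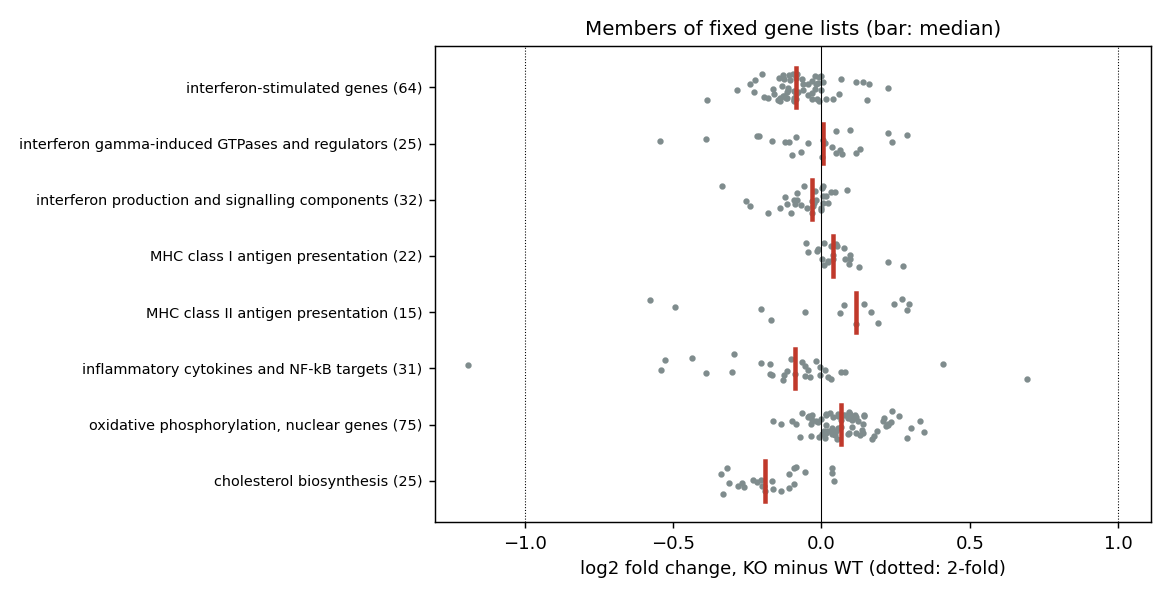
Log2 fold changes (KO minus WT) of the tested members of 8 fixed gene lists, with points for genes, red bars for medians, dotted lines at 2-fold and the number of tested members in brackets. Medians lie between -0.19 (cholesterol biosynthesis) and 0.12 (class II antigen presentation).

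The core macrophage list held 2 genes that passed over all genes, Lyz1 and Lyz2, and 4 adjusted over the list alone, Timd4 and Vsig4 being added. Vsig4, a complement receptor gene, was at 0.662 ± 0.232 CPM in KO and 2.26 ± 1.11 CPM in WT (SD, n = 3), with a log2 fold change of -1.77 and a standard error of 0.44, and did not pass over all genes. With the added covariate Vsig4 passed (edgeR adjusted p = 0.0348), within a range from 0.0348 to 0.999947. As a list it did not pass (camera adjusted p = 0.656), with a median of -0.00212, a mean of -0.08 and a camera direction upward, so that these measures differ in sign. Of its 34 members, 28 had a 95% interval within 1.5-fold.

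Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were slightly higher in KO as a list. Of 75 tested members 59 were above 0, with a median log2 fold change of 0.07 (camera adjusted p = 1.12e-06, adjusted p = 0.733 with an estimated correlation). No member passed in edgeR, DESeq2 or limma voom without a covariate, and 10 had an unadjusted p under 0.05 in edgeR. Atp5l was at 88.8 ± 3.27 CPM in KO and 72.0 ± 4.46 CPM in WT (SD, n = 3), with a log2 fold change of 0.30. With the added covariate Atp5l passed (edgeR adjusted p = 0.0140), within a range from 0.0140 to 0.99984. Of the other members, Cox7a2, Atp5k and Sdhc had 0.35, 0.33 and 0.21. The mean of the list was higher in each KO library than in each WT library (exact two-sided permutation p = 0.1). The closest values were 0.018 in KO 2 and 0.007 in WT 3, with standard deviations of 0.03 among KO and 0.04 among WT libraries. Such separation was not particular to this list. It was also seen for the m1A enzymes and for 2 lists that did not pass, the other tRNA modification enzymes and the immune checkpoint and co-stimulation genes. Chance alone gives such separation for 10% of lists. In the remaining lists called, KO and WT means overlapped. Their exact two-sided permutation p lay between 0.2 (such as cholesterol biosynthesis) and 0.6 (interferon-stimulated genes). The oxidative stress response list was higher as well, with 21 of 25 members above 0 and a median of 0.10 (camera adjusted p = 0.000844, adjusted p = 0.733 with an estimated correlation). Hmox1, which degrades haem, was at 951 ± 57.6 CPM in KO and 818 ± 103 CPM in WT (SD, n = 3), a log2 fold change of 0.22, and Esd, Taldo1 and Blvrb had 0.16, 0.14 and 0.13. No member of this list passed, and 3 had an unadjusted p under 0.05. Its call was also lost without KO 1 and WT 2 together (camera adjusted p = 0.0652), an alternative added after the data were seen, within a range from 1.75e-05 to 0.733.

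Cholesterol biosynthesis genes were lower in KO as a list, with 22 of 25 members below 0 and a median log2 fold change of -0.19 (camera adjusted p = 4.32e-06, adjusted p = 0.739 with an estimated correlation). Sqle, which encodes squalene epoxidase, was at 20.9 ± 1.76 CPM in KO and 26.1 ± 3.96 CPM in WT (SD, n = 3), a log2 fold change of -0.32, and Cyp51, Fdft1 and Sc5d had -0.31, -0.34 and -0.19. No member passed, and 1 had an unadjusted p under 0.05. The list mean stood at 0.31 in WT 2 and between -0.13 and -0.02 in the other libraries, relative to the mean of the 6 libraries. Without WT 2 the call was lost (camera adjusted p = 0.351), within a range from 4.53e-10 to 0.739 over 16 alternatives.

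The enzymes that write, erase or bind m1A passed as a list (13 tested, camera adjusted p = 0.0212, adjusted p = 0.733 with an estimated correlation), and Trmt61a was the only member that passed on its own. With Trmt61a left out the list had an adjusted p of 0.981, an alternative added after the data were seen. The call was also lost without KO 2 (camera adjusted p = 0.148), without WT 1 (0.0977) or without WT 3 (0.0680), within a range from 0.0121 to 0.981. Alkbh7, Fto and Ythdf2 had log2 fold changes of 0.24, 0.08 and 0.08. The other tRNA modification enzymes did not pass as a list (54 tested, median -0.01, camera adjusted p = 0.684). Trmt10b, Dus4l, Thg1l and Pus7 had -0.46, -0.76, 0.36 and 0.21, and 0 members of this list passed in edgeR, DESeq2 or limma voom, with 3 at an unadjusted p under 0.05.

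Markers of other cells varied from library to library within both genotypes. Relative to the mean of the 6 libraries, the cell cycle list stood at -0.46 in KO 1 and -0.36 in WT 2, and at 0.39 in KO 3 and 0.38 in WT 3. The neutrophil list stood at -0.38 in KO 1 and 0.40 in WT 3, and the list of mast cells, basophils and eosinophils at -0.68 in KO 1 and 0.72 in WT 3. None of these 3 lists passed between genotypes (camera adjusted p = 0.584, 0.691 and 0.124). Fibroblast, stromal and endothelial markers lay higher in KO as a list (20 of 23 members above 0, median 0.24, camera adjusted p = 0.00109, adjusted p = 0.739 with an estimated correlation), with list means of 0.51 in KO 2 and -0.41 in KO 1. Cxcl12, a chemokine gene of stromal cells, was at 27.8 ± 4.80 CPM in KO and 21.1 ± 0.882 CPM in WT (SD, n = 3), and Pdgfra and Myl9 had log2 fold changes of 0.56 and 0.49. Ibsp, at 0.931 ± 0.342 CPM in KO and 1.79 ± 1.36 CPM in WT (SD, n = 3), had -0.94 with a standard error of 0.61, and between -1.39 and -0.22 when each library was left out. That call was lost without KO 2 (camera adjusted p = 0.610) or without WT 2 (0.188), within a range from 1.81e-19 to 0.863. Erythroid and megakaryocyte markers were higher as a list (10 of 13 members above 0, median 0.29, camera adjusted p = 0.0126, adjusted p = 0.733 with an estimated correlation), and adjusted over the list alone Vwf (0.27) and Tfrc (-0.21) passed in opposite directions. Over all genes Vwf passed only with the added covariate (edgeR adjusted p = 0.0497), within a range from 0.0497 to 0.999947. Pf4 and Gp9, which encode platelet proteins, had 0.21 and 1.03. Tfrc, Pf4 and Vwf stood at 229, 135 and 77.6 CPM in KO, against 1.99 CPM for Gp9, and Pf4 was also a member of the chemokine list. Whether these transcripts came from other cells or from the macrophages was not tested. The erythroid and megakaryocyte call was lost without KO 2 (camera adjusted p = 0.112), without KO 3 (0.121) or without WT 2 (0.0970), within a range from 0.000110 to 0.733.

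**Figure D4:**
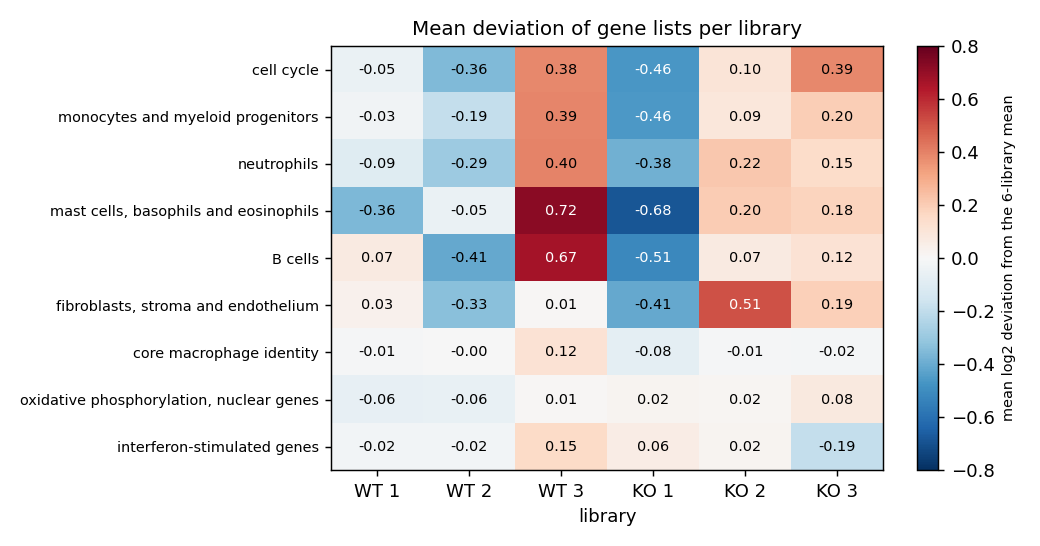
Mean deviation of 9 gene lists in each library from the mean of the 6 libraries, on the log2 scale, with red for higher and blue for lower values. Marker lists of cycling cells and of other cell types vary among libraries of the same genotype, from -0.46 (KO 1) to 0.39 (KO 3) for the cell cycle list.

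The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in each of the 6 libraries. Ddx3y was at 80.2 ± 7.43 CPM in KO and 75.3 ± 2.59 CPM in WT (SD, n = 3), and the log2 fold changes of the 4 genes lay between -0.04 and 0.09. Xist was not analysed here.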

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

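The settings named here as added were chosen after the data were seen. Trmt61a, Lyz1 and Cd163 kept their direction and call under each alternative. Lyz2 kept its direction, but lost its call without KO 2, without WT 1 and under the minimum fold change. The count of 4 genes stayed between 3 and 6 under other normalizations, filters, limma voom and a minimum fold, and ran from 3 to 5 when each library was left out in turn. DESeq2 called 17 genes, 16 of them lower in KO. With the first component of within-genotype deviations as an added covariate 31 genes were called, 9 higher and 22 lower. The cause was not tested. Libraries with the same number did not deviate together throughout (correlations across genes of 0.03, -0.13 and 0.25, genes not being independent replicates). With 3 libraries per genotype this cannot exclude pairing, which the labels do not state. With a replicate block 8 genes and 15 lists were called, and not every library correlated best with its own number. The 13 lists called fell to 0 with an estimated correlation and ran from 8 (without KO 2) to 18 (without KO 1) when each library was left out. With fry, which does not compare a list with other genes, 0 were called.

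Some results that did not pass changed sign. The camera direction of the interferon gamma list was downward, although 14 of its 25 members lay above 0. It turned upward without a count filter (camera adjusted p = 0.786) and without KO 3 (0.232) or WT 2 (0.485). The camera adjusted p of this list ran from 0.232 to 0.807 when each library was left out. The core macrophage list reversed with the added covariate (adjusted p = 0.863) and with Lyz1, Lyz2 and Trmt61a left out (0.154). When each library was left out, the log2 fold change of Kdm5d ran from -0.0823 to 0.0755 and that of Trmt6 from -0.107 to 0.0425, with a positive value only without WT 1. With KO 1 and WT 2 both left out, H2-Oa had 0.0929 and Kdm5d -0.0115, and 6 genes and 10 lists were called. The cause was not tested. Leaving out mitochondrially encoded genes was not run, since 0 were in the table. Depth limits what can be seen for genes at or under 1 CPM, such as Slc1a3, Timd4 and H2-Oa in KO.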

Other observations

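Several lists not described so far lay slightly higher in KO. Glycolysis and hypoxia genes had 28 of 35 members above 0 and a median log2 fold change of 0.07 (camera adjusted p = 0.00958), Myc targets and ribosome biogenesis genes 32 of 40 and 0.07 (0.0126), cytosolic ribosomal proteins 52 of 79 and 0.04 (0.0126), and genes of the integrated stress response 27 of 35 and 0.08 (0.0203). With an estimated correlation their adjusted p was 0.739, 0.741, 0.741 and 0.739. After trends with transcript length and GC content were removed, an alternative added after the data were seen, the ribosomal protein list no longer passed: its median went from 0.0336 to 0.0231 and its unadjusted camera p from 0.00138 to 0.197, while the list mean had standard deviations of 0.05 among KO and 0.04 among WT libraries. Of the other 12 lists called, 11 kept an unadjusted camera p under 0.05 after that removal. This comparison ran camera on log2 CPM values, where the m1A enzyme list did not reach 0.05 before the removal either (unadjusted camera p of 0.156, and 0.181 after), unlike in the test on counts (0.00727). Cytosolic aminoacyl-tRNA synthetases did not pass (24 tested, median 0.02, camera adjusted p = 0.496), nor did translation initiation and elongation factors (45 tested, median 0.00451, camera adjusted p = 0.496), for which all 45 members had a 95% interval within 1.5-fold. Lysosomal genes did not pass either (45 tested, median 0.03, camera adjusted p = 0.0680). In the phagocytosis list Timd4 passed adjusted over the list alone, and in the checkpoint and co-stimulation list Tnfsf10 and Vsig4 did.

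Of the tests that follow, those of Lyz1 and Lyz2 and that of liver RNA for Cd163 were chosen only after the result was seen, as was the value without WT 2 for the hepatocyte genes. The real split of the 6 libraries gave 4 genes, the highest of the other splits gave 557, and the remaining splits gave 0. Counting the real split itself, 2 of the 10 splits gave at least 4 genes. For lists the real split gave 13 and the highest other 18, and 4 of the 10 splits, the real one included, gave at least 13. Every split called lists, the fewest being 5, so a call alone does not set genotype apart from other splits. With 10 splits no share under 0.05 can be reached. The split that called 557 genes set KO 1, WT 1 and WT 2 against the rest, which points to a structure among the libraries that does not follow genotype. The first principal component, with 32.9% of the variance, also set KO 1 and WT 2 furthest to one side. The second component, with 20.8%, did separate the genotypes, with KO between -15.3 and -11.3 and WT between -1.69 and 21.6. Chance alone separates 3 against 3 libraries on a given component in 10% of cases.

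Lyz1 was higher while its neighbour Lyz2 was lower. If reads of Lyz2 had been counted for Lyz1, Lyz1 would have followed Lyz2 downward, whereas its log2 fold change was 2.65. That rise is the pattern to be explained, so it speaks against this reading without being a separate test. The longest transcripts share 16.1% of the 50-base stretches of Lyz1 and 0 of the 150-base stretches. Altered transcripts of the Cre-carrying Lyz2 allele may have been counted for Lyz1, and no gene-level value decides this. The gain of Lyz1 amounts to 1.71% of the Lyz2 level in KO, which speaks neither for nor against it. A changed stretch of chromosome 10 also stays open: 8.57% of the 35 genes within 5 Mb (Cpsf6, Irak3 and Yeats4) had an unadjusted p under 0.05 against 3.08% of the tested genes with a position, Lyz1 and Lyz2 left out, and a share of 0.103 of random windows reached as much. Cre and the loss of Trmt61a occur in the same libraries, so an effect of either on Lyz1, Lyz2 or any other gene cannot be told apart. Lyz2 carries the Cre insertion, so its fall to 50.4% of the WT level cannot be read as a response to Trmt61a loss.

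Cd163 was lower, and genes expressed in liver lay lower as a list, with 0 of 36 hepatocyte genes passing over all genes and 2 at an unadjusted p under 0.05. For these genes the values that liver RNA in WT libraries would need were there, with a median log2 fold change of -0.70 and 32 members below 0 (camera p = 1.87e-06, p = 0.257 with an estimated correlation), and WT 2 alone carried most of it: the summed level was 71.7 CPM in WT 2 and between 32.8 and 38.2 CPM in the others, and the median without WT 2 was -0.20. Of these genes 4 reached 1 CPM in KO, and Alb, the most abundant, was at 30.2 CPM in WT 2 and between 15.8 and 19.5 CPM elsewhere. Liver RNA as the source of the Cd163 difference is argued against by its log2 fold change of -1.61 without WT 2 (standard error 0.14, edgeR adjusted p = 0.00193; range over 16 alternatives 4.21e-26 to 0.0151), and by an excess in WT of 18.6 CPM for Cd163 against 11.9 CPM for all hepatocyte genes together. Fewer macrophages of a tissue-resident kind and a weaker glucocorticoid response stay open: the medians of -0.0615 (21 genes) and 0.00427 (24 genes) lay within the bounds written to exclude them, but both lists leave out Cd163, the resident list also leaves out Timd4 and Vsig4, 19 of its 21 genes reached 1 CPM in KO and 15 lay below 0, and 12 of the 24 glucocorticoid genes lay below 0.

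The oxidative phosphorylation list was shifted up in KO. A trend of fold changes with transcript length and GC content is argued against as the whole cause, since the median log2 fold change was 0.0687 before and 0.0619 after the trend was removed over the 74 of 75 members with a length, and its camera p stayed under 0.05. The call stayed without KO 1 and WT 2 together (camera adjusted p = 0.000138), an alternative added after the data were seen, so it does not rest on these libraries alone. The call also stayed with the added covariate (camera adjusted p = 7.97e-07), which was derived from the same counts. It was lost with an estimated correlation (camera adjusted p = 0.733). Fry, which asks whether the genes move one way and not whether they differ from other genes, gave an adjusted p of 0.644. Over 16 alternatives the adjusted p ran from 1.00e-07 to 0.733, and structure among the libraries as the source of the shift stays open.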
